A study of Rattus norvegicus with 2 samples.

How the data were processed

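Gene expression was measured in neonatal rat ventricular myocytes, beating heart muscle cells isolated from the ventricles of newborn rats, on 2 one-colour Affymetrix arrays labelled with biotin. Per the labels, one array holds RNA of cells transduced with an adenovirus that carries a short hairpin RNA (shRNA) against Mef2d, and the other holds RNA of cells given an shRNA against lacZ, a bacterial gene that rat cells lack, as the negative control. The series' design text says that each array was a pool of RNA from 6 biological replicates, harvested 3 days after transduction. The extraction protocol in the labels instead speaks of 3 biological replicates per condition after pooling and calls the cells myotubes, and the difference is not resolved here. With 1 array per condition there is no spread between replicates, so no p-value or error of a difference can be given, and the number of arrays limits the precision of every value.

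The deposited values are on the log2 scale and were made with RMA (background correction, quantile normalization between arrays and a summary of the probes of each probe set) and the affy package, version 1.36.1, per the submitters' processing notes. The role of each tool in the notes and the probe set definition are not given in the sources used here. RMA values carry no detection call, so a low value cannot be told from background. RMA also compresses differences of dim probe sets. The value table holds 19239 probe sets. Over all of them the array labelled lacZ shRNA had a median of 6.29 and the array labelled Mef2d shRNA a median of 6.28, with ranges of 2.12 to 12.98 on both, and the 2 sets of values were close but not identical in distribution. Every deposited value column was used.

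Gene names came from the platform annotation, whose symbols can be old. It pairs 16592 probe sets with exactly 1 gene symbol, none with several, and leaves 2647 unnamed here. No symbol had more than 1 probe set. The number in a probe set's identifier was a gene identifier of the rat reference table (assembly GRCr8) for 16453 named probe sets, and for 16420 of these the symbol or a synonym was the same. Coordinates are not printed, because the probe sets' genome build is not given in the sources used here.

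From these values the difference of each gene was computed as the array labelled Mef2d shRNA minus the array labelled lacZ shRNA, without further normalization. Named genes with a mean over both arrays under the 30th percentile (log2 4.85) were left out, which kept 11614 genes and removed 4978. A gene was counted as higher or lower when the arrays differed by at least 1.5-fold, 0.58 on the log2 scale. To set this beside the scatter between the arrays, a robust SD (scaled median absolute deviation) of the differences was taken in 20 bins of genes of similar level. It ranged from 0.11 to 0.21, so the threshold lies 2.85 to 5.37 robust SDs from 0. This scatter mixes measurement noise with any real differences and is not a replicate error.

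A set of 24 gene lists, with 554 distinct symbols, was fixed before the data were examined. It covers contractile, calcium handling, metabolic, cell cycle, stress and inflammatory genes and markers of other cell types that a ventricular preparation could hold. Of the symbols, 466 matched directly and 10 through an older symbol with the same gene identifier. A further 18 matched only an unnamed probe set and 60 matched none. Each list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. The percentile describes these 2 arrays and is not a p-value. The central 95% runs from percentile 2.5 to 97.5. The Dlk1-Dio3 list had fewer than 3 members past the level filter and received no percentile. The genes named in the text were set by a rule fixed before the data were examined, which takes the MEF2 family, the 15 genes with the largest difference in each direction, and in each list the 2 members with the largest difference in each direction.

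Both steps were tested on simulated data with the levels and the scatter of this comparison over 11614 genes. All 50 genes changed 2-fold passed the 1.5-fold threshold, as did all 50 changed 3-fold and all 50 changed 4-fold. Of 50 genes changed 1.3-fold, 9 passed. Of 11384 unchanged genes, 9 passed. A simulated list of 30 genes shifted by 0.25 on the log2 scale lay at percentile 100, and 2 of 100 unshifted lists lay outside the central 95%. The simulation draws normal noise for each gene independently and adds each change to the summarized values, so it skips the compression by RMA. The real differences had an SD of 0.20 against a robust SD of 0.17, so normal noise leaves out their wider tails. The simulated shares that passed are therefore not rates for the genes counted here. The simulation also leaves out any variation between pools or cultures and the co-regulation of genes in a list. The rate for unshifted lists therefore holds only for unrelated genes.

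Alternatives were other level filters, 3 other scalings (centring each array on its median, a loess of the difference on level with a span of 0.3, and quantile normalization of the 2 arrays), other size thresholds, the mean of a list, and random lists not matched on level. Matching unnamed probe sets to the reference table by gene identifier was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.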

Results

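The study compared cultured neonatal rat ventricular myocytes in which an adenoviral shRNA targeted Mef2d, which encodes a member of the MEF2 family of muscle transcription factors, with cells given a control shRNA against lacZ. The cells came from rat pups of 1 to 2 days. Each condition was measured once, on 1 array with pooled RNA, so the values below have no replicate error and each difference describes these 2 arrays. Levels are log2 RMA values, and each difference is the array labelled Mef2d shRNA minus the array labelled lacZ shRNA. Across all 19239 probe sets the 2 arrays had a Pearson correlation of 0.996. This is a correlation across genes, which are not independent replicates.

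The targeted transcript did not have the direction that its label implies. Mef2d (probe set 81518_at) had a level of 8.22 on the array labelled lacZ shRNA and 8.94 on the array labelled Mef2d shRNA, which is 1.64-fold higher on the latter (log2 difference 0.71). The difference was 4.57 robust SDs above the centre of genes of similar level, and 41 of 11614 genes, Mef2d included, were at least as much higher. Mef2c, a family member needed for heart development, had levels of 8.64 and 8.45 (difference -0.19). The level of Mef2b was 5.14 on the array labelled lacZ shRNA and 5.08 on the array labelled Mef2d shRNA. Mef2a was not analysed here. Because the measured Mef2d level goes against the labels, the arrays are called by their labels throughout, and every direction below would turn if the labels were exchanged.

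Of the 11614 genes past the level filter, 98 (0.844%) were at least 1.5-fold higher and 62 (0.534%) at least 1.5-fold lower on the array labelled Mef2d shRNA. The largest positive difference was that of Casq2, the calcium-binding protein of the cardiac sarcoplasmic reticulum, at 2.67-fold (10.18 on the array labelled lacZ shRNA, 11.60 on the array labelled Mef2d shRNA). Slco5a1, an organic anion transporter family member, was 2.40-fold higher. Apobec2, a muscle-enriched member of the cytidine deaminase family, was 2.30-fold higher, and Pfn2, an actin-binding profilin, 2.24-fold. Sypl2, a protein of the muscle triad membrane, was 2.19-fold higher and Pank1, which starts coenzyme A synthesis, 2.06-fold. Also at least 2-fold higher were P2rx1, an ATP-gated channel, at 2.31-fold, Atp6v1g2, a proton pump subunit, at 2.20-fold, and Depdc1 at 2.14-fold. The remaining genes among the 15 largest were Slc39a2, Krtap31-1, Pdlim1, Pstpip2, Armcx2 and Rdh2, with differences from 0.98 down to 0.90 on the log2 scale.

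The largest negative difference was that of Lcn2, the iron-binding acute phase protein lipocalin 2. It was 3.63-fold lower on the array labelled Mef2d shRNA (6.64 on the array labelled lacZ shRNA, 4.78 on the other). Mcm6, a subunit of the replicative helicase, was 2.51-fold lower, Ccl20, a chemokine, 2.30-fold, and Lin9, a subunit of a complex that controls cell cycle genes, 2.22-fold. The helicase subunits Mcm3 (1.99-fold) and Mcm5 (1.87-fold) were also lower, as were Ccne2, or cyclin E2 (1.78-fold), the small GTPase Rac2 (1.98-fold), the urokinase gene Plau (1.85-fold) and the interferon-induced gene Mx2 (1.84-fold). RGD1561425 had levels of 6.20 on the array labelled lacZ shRNA and 5.19 on the other. Lppr4, Flrt3, Rab15 and Pla2g2a completed the 15 largest, with differences between -0.95 and -0.82. P2rx1, Depdc1 and Pstpip2 had levels of at most 5.03 on the array labelled lacZ shRNA, and Lin9 and Lcn2 of at most 4.78 on the array labelled Mef2d shRNA, close to the level filter of 4.85, so their folds are less certain.

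**Figure D1:**
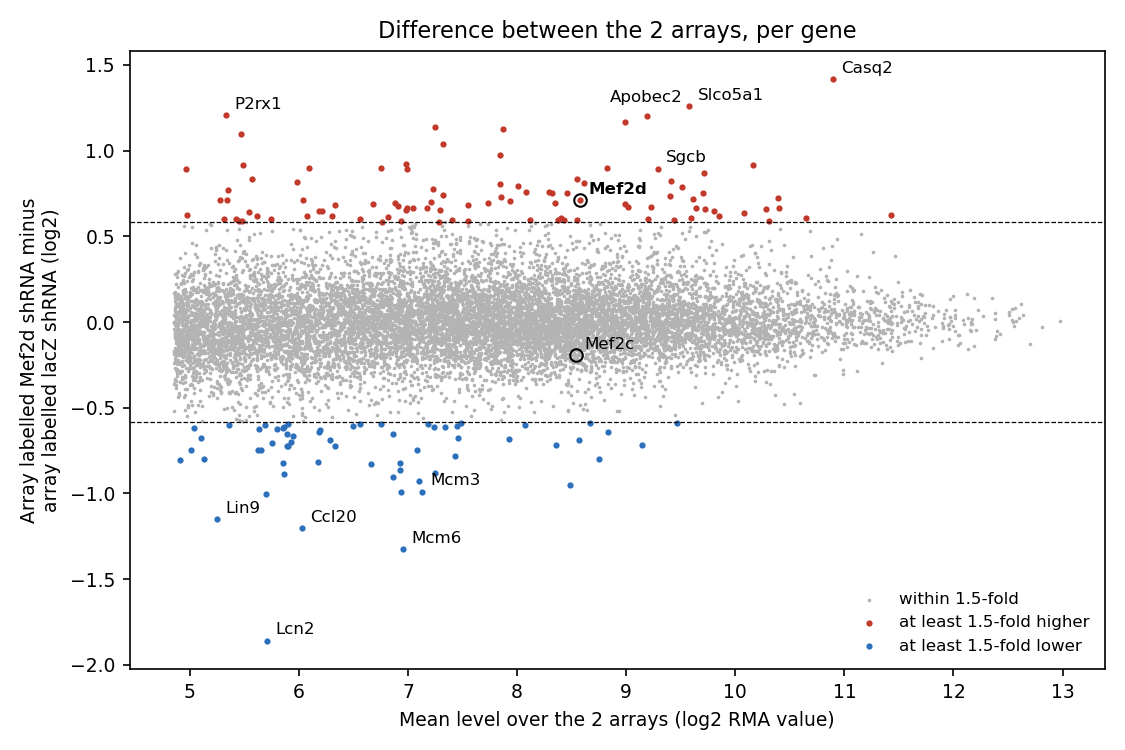
Each point is 1 of 11614 genes, with its mean level over both arrays (log2 RMA value) on the x axis and the difference, array labelled Mef2d shRNA minus array labelled lacZ shRNA (log2), on the y axis. Dashed lines mark 1.5-fold; red points are the 98 higher and blue points the 62 lower genes, and Mef2d (circled) lies among the higher ones at 0.71 while Mef2c (circled) lies at -0.19.

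**Figure D2:**
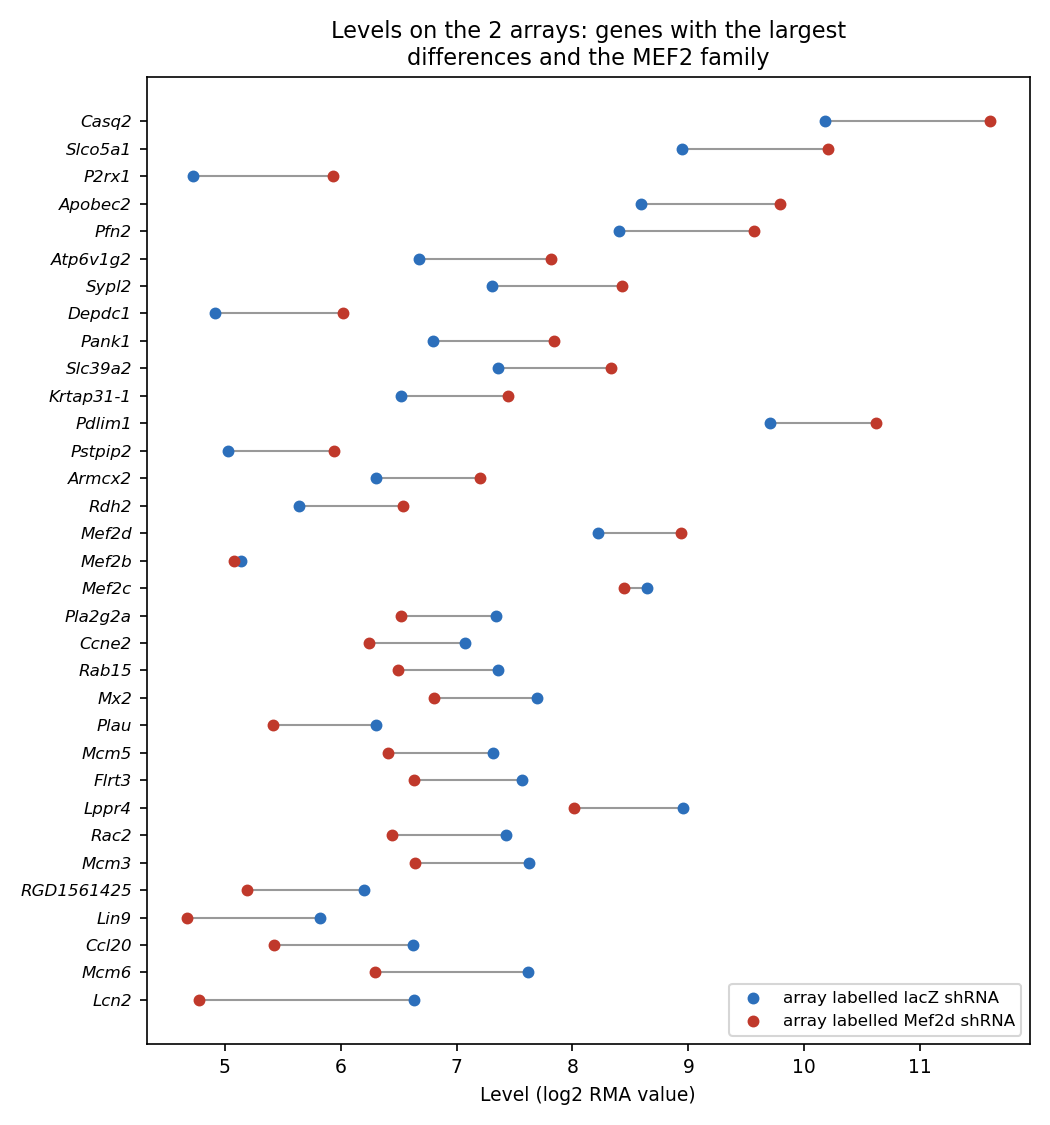
Levels (log2 RMA value, x axis) of the 15 genes with the largest difference in each direction and of Mef2b, Mef2c and Mef2d on the array labelled lacZ shRNA (blue) and the array labelled Mef2d shRNA (red), 1 array each, with no error bars because there are no replicates. Casq2 and Lcn2 have the widest gaps, and Mef2d is further right on the array labelled Mef2d shRNA.

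Genes of the contractile apparatus tended to be higher on the array labelled Mef2d shRNA, by small amounts. The 20 thick and thin filament genes past the level filter had a median difference of 0.10 (percentile 99.5 of matched random lists). Of these, 11 were above 0 and 9 below, and none differed by 1.5-fold. The M-band genes Myom1 and Myom2 had the largest positive values (0.48 and 0.45). The largest negative values were those of Myh6, the fast alpha myosin heavy chain of the heart, at -0.46 and of Myom3 at -0.26. The 31 Z-disc, costamere and intercalated disc genes had a median of 0.09 (percentile 99.8), with 21 above 0. At least 1.5-fold higher among them were Sgcb, or beta-sarcoglycan (1.86-fold), and Mypn, or myopalladin (1.60-fold), and none was as much lower. The desmosome genes Dsp (-0.30) and Pkp2 (-0.24) had the largest negative values.

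Calcium handling and ion channel genes had a median of 0.07 over 27 members, at percentile 96.6, inside the central 95% of random lists. Their mean was 0.20, at percentile 100. In this list 3 genes were at least 1.5-fold higher and none lower. These were Casq2, the potassium channel gene Kcnh2 (1.60-fold) and Trdn, or triadin, which binds calsequestrin (1.59-fold; named after its value was seen). The calcium pump gene Atp2a2 and its regulator Pln, also named after their values were seen, differed by 0.06 each. The largest negative values among the calcium handling and ion channel genes were those of Asph (-0.18) and Kcna5 (-0.13), with 21 members above 0 and 6 below. Natriuretic peptide and hypertrophy-associated genes had a median of -0.04 over 14 members (percentile 12.4) with none past 1.5-fold. In this list Myh7 had the largest positive value (0.38) and Klf5 the largest negative value (-0.20). The 19 cardiac transcription factors and MEF2 co-regulators had a median of 0.02 (percentile 71.1), with the histone deacetylases Hdac9 (0.38) and Hdac4 (0.33) highest and Hopx (-0.23) lowest.

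Genes of fat oxidation and energy transfer were also higher on the array labelled Mef2d shRNA. Over 31 members the median was 0.16, with 22 above 0, and 1 of 10000 matched random lists had a median at least as high. Decr1, a mitochondrial enzyme that handles unsaturated fatty acids, was 1.67-fold higher and the only member past 1.5-fold. Mb, or myoglobin, had a difference of 0.50. Fabp3, the heart fatty acid binding protein, had the largest negative value, at -0.29, followed by Lpl (-0.19). Oxidative phosphorylation genes had a median of 0.06 over 35 members (percentile 97.9), and 25 were above 0. Of these, Ndufs3, a complex I subunit, was 1.52-fold higher, and Cox8b had a difference of 0.37. This list lay inside the central 95% after quantile normalization (percentile 94.995) and against random lists not matched on level (percentile 96.6). The 21 glycolysis and glycogen genes had a median of 0.02 (percentile 68.5), with the insulin-responsive glucose transporter gene Slc2a4 at 0.57 and the basal glucose transporter gene Slc2a1 at -0.31.

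Genes of the G1/S transition and DNA replication were lower on the array labelled Mef2d shRNA. Of 31 members past the level filter 28 were below 0, with a median of -0.33. None of 10000 matched random lists had a median as low. Of these 31 genes, 8 were at least 1.5-fold lower and none was as much higher. They were Mcm6, Mcm3, Mcm5, Ccne2 and, named after their values were seen, the licensing factor genes Cdc6 (1.74-fold) and Cdt1 (1.53-fold), the cyclin E1 gene Ccne1 (1.68-fold) and the helicase component gene Gins2 (1.56-fold). Cdc6 had a level of 4.50 on the array labelled Mef2d shRNA, under the filter's cut of 4.85, so its fold is less certain. The largest positive values in the list were 0.10 for Lig1 and 0.04 for Orc6l. Ccnd1 and Ccnd2, the D-type cyclin genes, had differences of 0.01 and -0.03 (named after their values were seen).

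The G2/M and mitosis list did not share that direction. Its 30 members past the level filter had a median of 0.10 (percentile 99.8), with 20 above 0. The kinetochore gene Ndc80 (1.86-fold) and the spindle checkpoint gene Bub1 (1.51-fold) were higher, and the lowest members were Cdc25c (-0.22) and the proliferation marker gene Mki67 (-0.21). Most of these genes were dim, and Ndc80 had a level of 4.52 on the array labelled lacZ shRNA. With only the 8 members at or above the median level of all named genes, the list median was 0.02 at percentile 56.8, so this shift rests on dim genes. Cyclin-dependent kinase inhibitors, pocket proteins and p53 targets had a median of -0.04 over 14 members (percentile 22.7), with Sesn1 at 0.35 and Rbl1 at -0.35. Apoptosis genes had a median of 0.02 over 20 members (percentile 67.3), where the survival gene Bcl2 had a difference of 0.48 and Xiap of 0.47, and Casp8 had one of -0.44. Neither list held a gene past 1.5-fold.

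Interferon-stimulated genes and an inflammatory gene list were lower on the array labelled Mef2d shRNA. Of 19 interferon-stimulated genes 18 were below 0, the median was -0.32, and none of 10000 matched random lists had a median as low. This list was set beforehand as a quality list. The random lists were already matched on level, so subtracting the loess of the difference on level could change little. The median was -0.32 (percentile 0) after it, so a trend of the difference with level does not account for the shift. Other causes of this shift were not tested. Past 1.5-fold were Mx2 (1.84-fold lower), Isg15 (1.61-fold) and Usp18 (1.51-fold; named after its value was seen), while Bst2, at 0.06, was the member above 0. Of the 12 genes past the level filter in the inflammatory list, which mixes cytokines and chemokines with genes of other kinds such as Lcn2, 10 were below 0, with a median of -0.31, and again no random list was as low. Lcn2, Ccl20 and Cxcl12 (1.68-fold lower; named after its value was seen) passed 1.5-fold, and Tnf had the largest positive value (0.27) from a low level of 5.1 on the array labelled lacZ shRNA. Macrophage and leukocyte markers were also lower (median -0.13 over 12 genes, percentile 1.86), with none past 1.5-fold. Immediate early genes had a median of -0.07 over 20 members (percentile 5.32; their mean of -0.08 lay at percentile 1.23), with Myc lowest (-0.32) and Arc highest (0.14). The 17 unfolded protein response genes had a median of 0.05 (percentile 84.9), with Edem1 at 0.25 and Sdf2l1 at -0.20.

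No marker past the level filter in the 5 lists of other cell types differed by 1.5-fold between the arrays. Fibroblast and extracellular matrix markers had a median of -0.04 over 26 genes (percentile 5.45; their mean of -0.06 lay at percentile 0.94), from Col6a3 at -0.39 to Ogn at 0.20, and 16 were below 0. Smooth muscle and pericyte markers had a median of -0.05 over 14 genes (percentile 10.7), from Lmod1 at -0.25 to Synpo2 at 0.17. Macrophage and leukocyte markers were mostly lower, with a median of -0.13 over 12 genes (percentile 1.86), Lyz2 and Ptprc lowest at -0.34 each and Tyrobp highest at 0.24. This list moved in the direction of the inflammatory and interferon lists, and lay inside the central 95% when only genes at or above the median level were kept (percentile 7.01) and when its mean was used (percentile 4.17). The 5 endothelial markers past the filter had a median of 0.00 (percentile 58.6), from Sox17 at -0.06 to Tek at 0.10. Without the level filter the median of 14 endothelial markers was -0.032 (percentile 48.6). The 3 erythroid markers past the filter had a median of 0.19 (percentile 96.3), with Hbb-b1 at 0.42. Without the level filter the median of 6 erythroid markers was -0.094 (percentile 21.6), so this list has no settled direction. Cytosolic ribosomal protein genes had a median of -0.03 over 19 members (percentile 12.7), with Rpl10a lowest at -0.26 and Rps15 highest at 0.19. None of the ribosomal protein genes differed by 1.5-fold either. In the Dlk1-Dio3 imprinted locus 2 genes were measured above the filter, Dlk1 (0.02) and RGD1566401 (-0.19), which the reference table lists as Meg3.

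Of the 23 lists with a percentile, 9 lay outside the central 95% of matched random lists, 5 above and 4 below. By chance 1.15 would lie outside if the genes of each list behaved like randomly drawn genes of similar level. Lists share genes and genes are co-regulated, so these percentiles describe how the lists stand on these arrays and do not show that a repeat would give the same.

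**Figure D3:**
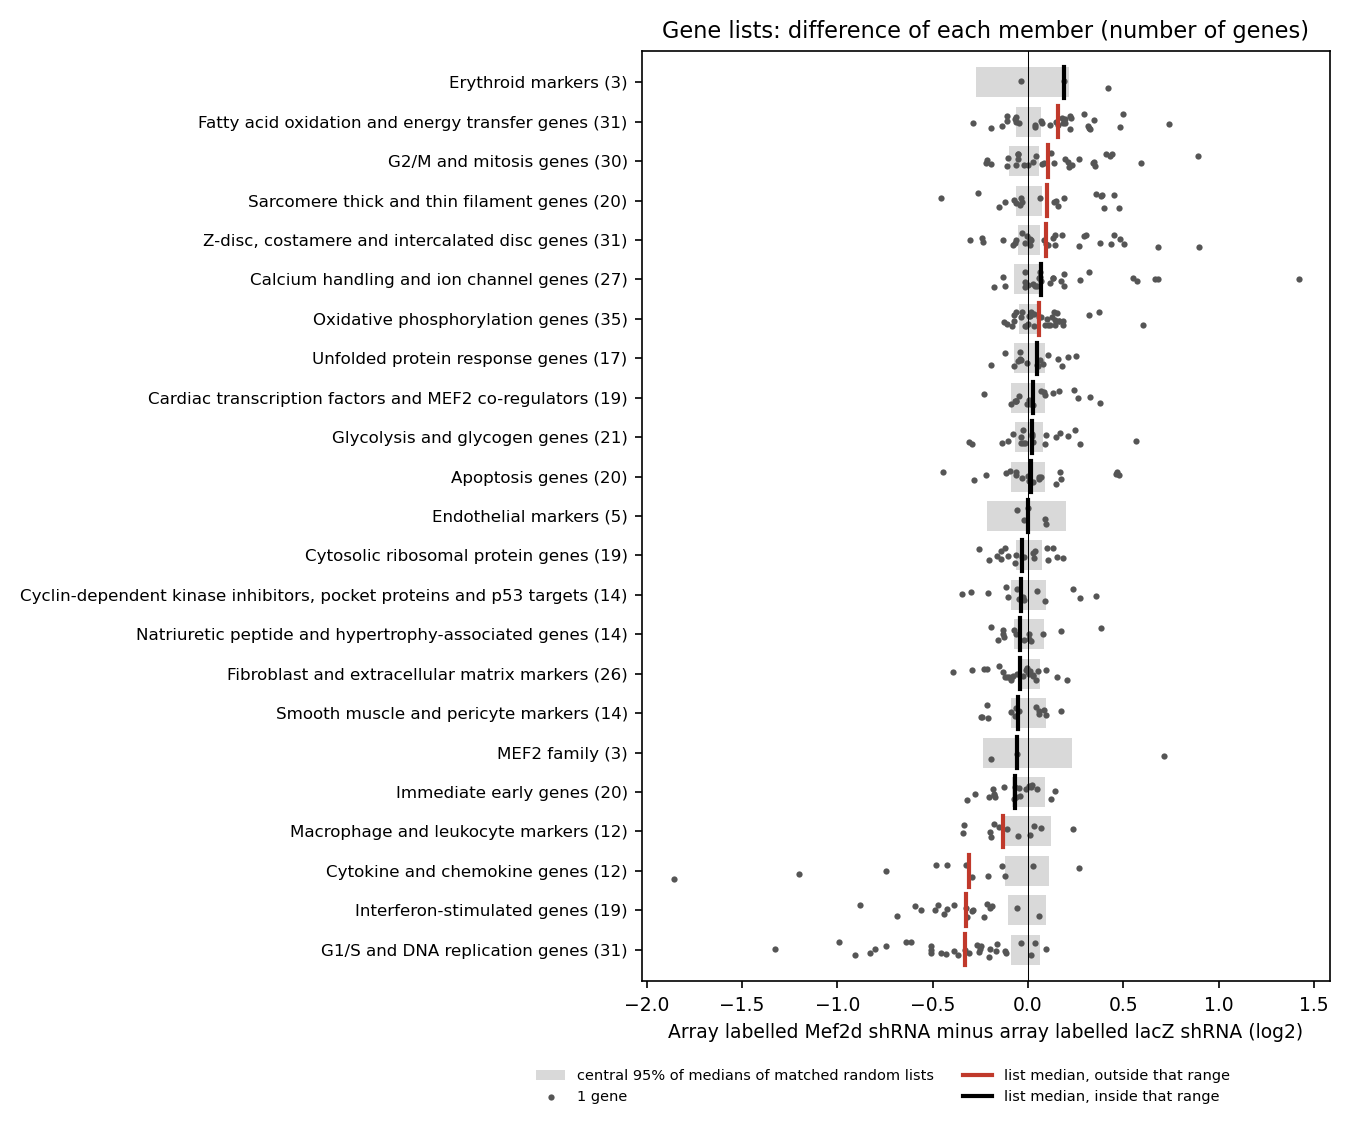
Each row is 1 gene list with the number of its genes past the level filter; grey points are the differences of its genes (array labelled Mef2d shRNA minus array labelled lacZ shRNA, log2, x axis), grey bars the central 95% of the medians of 10000 matched random lists, and vertical strokes the list medians, red where outside that range. The inflammatory list is the row titled cytokine and chemokine genes. The G1/S, interferon and inflammatory lists lie to the left at -0.33, -0.32 and -0.31, and the fatty acid list lies to the right at 0.16.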

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

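All alternatives were planned except the one that names further probe sets by gene identifier, which was added after seeing the data. The Mef2d difference lay between 0.71 and 0.73 under the other scalings, and a level filter cannot change it. The count of genes at least 1.5-fold higher (98) became 9 at 2-fold, 408 at 1.3-fold and 177 beyond 3 robust SDs of genes of similar level, and the count lower (62) became 5 at 2-fold, 287 at 1.3-fold and 82 beyond 3 robust SDs. Keeping only genes at or above the median level left 74 higher and 30 lower genes among 8296, where the cause of the larger loss of lower genes was not tested, and brought the G2/M list to 0.015 with 8 members. Without a level filter the erythroid list was at -0.094 with 6 members. The inflammatory list was at -0.21 with 17 members without a level filter, and at -0.25 with 8 members at or above the median level. With means in place of medians the calcium handling list was at 0.20 and the inflammatory list at -0.46, the fibroblast and immediate early lists fell outside the central 95% (percentiles 0.94 and 1.23), and the macrophage list fell inside it (4.17). The other scalings shared 90 to 98 of the higher genes and 55 or 56 of the lower genes with the values as deposited, moved the median of all genes by at most 0.01, and 8 or 9 of the 9 lists remained outside the central 95%. The calcium handling list lay outside it without a level filter (percentile 99.3) and with the added names (percentile 99.5). Of the 114 other named genes, whatever the size of their difference, 2 changed sign under at least 1 of the other scalings, and the larger of their reported differences was 0.039 in size. The alternatives for several probe sets per gene and for probe sets with several symbols were not run, because neither occurs here. No replicate could be left out and no paired analysis was possible because each condition has 1 array. Low signal limits the genes near the level filter.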

Other observations

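All genes in this paragraph were chosen after their values were seen, from those past 1.5-fold, and stand for no tested group. On the array labelled Mef2d shRNA the membrane repair gene Trim72 was 1.75-fold higher, the caveolin gene Cav3 1.61-fold and the kinase gene Dmpk 1.66-fold. The myosin genes Myl1 (1.79-fold) and Myh3 (1.76-fold), better known from skeletal and embryonic muscle, were also higher, as was the taurine transporter gene Slc6a6 (1.65-fold). Cxadr, which encodes the coxsackievirus and adenovirus receptor, was 1.58-fold higher (9.95 on the array labelled lacZ shRNA, 10.61 on the other). Among lower genes outside the lists were Wdhd1 (1.55-fold), Cdca7 (1.57-fold) and Donson (1.51-fold). Penk (1.74-fold), Sfrp2 (1.77-fold), Mmp12 (1.64-fold) and C4b (1.68-fold) were lower too. Of 1402 unnamed probe sets past the level filter, 16 were at least 1.5-fold higher and 11 at least 1.5-fold lower.

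In the paragraphs below, the tests of exchanged labels, scaling and array variation for Mef2d, of the myocyte share, of the share of cycling cells and of the size of the fibroblast difference were chosen after the results were seen, and the other tests were written before. The first pattern is the 0.71 higher Mef2d level on the array labelled as its knockdown, a difference of 4.57 robust SDs. Other scalings did not remove it, and the lowest value over 3 of them was 0.71. The deposited values were already quantile normalized and these scalings moved the median of all genes by at most 0.01. The scaling test could therefore hardly have come out otherwise. A candidate explanation is that the labels of the 2 arrays are exchanged, in which case Mef2d would be at 61.0% of its control level, but this rests on the same value that raised it and was not tested independently. Chance variation between single arrays stays open because no replicate measures it, although only 0.353% of genes were as much higher. A real rise of the Mef2d transcript in cells that received the shRNA was not tested, and no measurement used here shows which virus a pool received.

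The second pattern is the shift of the contractile lists. One change in the share of myocytes would move genes found only in myocytes alike. The differences of the 78 members, which include the calcium handling list, had an interquartile range of 0.33. This lies above the upper end of the central 95% of matched random lists (0.24). It would argue against such a change as the whole cause only if the members were restricted to myocytes. That condition was not tested, and Des is also in the smooth muscle list, so the range does not decide. A contribution from the makeup of the pools stays open. Of the 4 lists set for this test, 3 (fibroblast, smooth muscle and macrophage) had medians below 0 at the reported level filter. The endothelial median was 0.00. Without a level filter the endothelial median was -0.032 over 14 markers, and all 4 lists were below 0. Those signs were predicted for a different share of other cell types. However, the endothelial median then lay at percentile 48.6 of matched random lists, so its sign carries no information. The test turns on the filter and cannot decide. The erythroid list, not part of the test, was at 0.19 with the filter and -0.094 without it. The shRNA itself, named by the design, also stays open.

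The third pattern is the low G1/S list beside a high G2/M list. A lower share of fibroblasts would have to lower the fibroblast markers by about as much as the G1/S list, whose median was -0.33. Their median was -0.042 and their lower quartile -0.117, which argues against it as the whole cause. The size comparison is less certain for the brightest markers, such as Sparc and Vim (12.53 and 12.49 on the array labelled lacZ shRNA). These lie near the top of the range of 12.98, where the differences of all genes had the smallest scatter (robust SD 0.11). The fibroblast test written before could not decide. The list lay on the side of the G1/S list but inside the central 95% (percentile 5.45), while its mean lay outside (percentile 0.94). A smaller contribution of the fibroblast share stays open. A lower share of cycling cells would lower both lists, yet the G2/M list was at percentile 99.8 as reported and at 56.8 at its lowest over the level filters. Among the 8 G2/M members at or above the median level the lowest, Mki67, was at -0.21, above the G1/S median of -0.38 at that filter, which argues against it as the whole cause. A difference in cell cycle progression tied to the shRNA, and variation between single arrays, may contribute but were not tested.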
